A study of Saccharomyces cerevisiae with 12 samples.

How the data were processed

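The study measured RNA in log-phase cultures of Saccharomyces cerevisiae of the W303 background. It compared wild type (WT) with strains carrying the tup1(S649F) point mutation, in cells of the MATa and of the MATalpha mating type. Tup1 is the corepressor that acts together with Cyc8 and is brought to promoters by DNA-binding proteins; the series title asks about a coactivator function of it. Per the labels, cells grew at 30 °C in a rich yeast extract and peptone medium with added adenine and 2% dextrose, and were harvested at an optical density of 0.6 to 0.8 at 660 nm. Total RNA was extracted with phenol and chloroform, spun through a caesium chloride gradient and column-purified, and ribosomal RNA was depleted in a stranded Illumina total RNA library preparation with paired-end sequencing. There were 4 strains with 3 replicates each, 12 libraries in all. The labels do not say whether the replicates of a strain are separate cultures, so the p-values measure the spread among these samples only; each of the 4 groups is a single strain.

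The values used are raw read counts per gene, which the authors deposited as 1 table with 6219 genes and 1 column per library. Per the submitters' processing notes, cutadapt 2.8, STAR 2.7.3 and featureCounts 1.6.3 of the Subread package were used with the yeast builds sacCer3 and R64. Which tool did which step, the strand setting of the counting and the treatment of reads with several positions are not given in the sources used here. Genes that share reads with a near-identical copy (the flocculins FLO1, FLO5 and FLO9, the hexose transporters HXT6 and HXT7 or HXT13 and HXT15, the maltases MAL12 and MAL32, the seripauperins, the COS and Y′ genes near telomeres, and pairs of ribosomal protein genes) are therefore uncertain between copies, and so are transfer RNA genes and genes that overlap another on the opposite strand.

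Identifiers were matched to the gene table of the R64 reference, which gave symbols, positions and gene classes for 5925 of them. The other 294 had no match, 276 of them transfer RNAs, and kept the identifier of the table. Library totals ran from 5657714 to 9300353 counts. The replicates of a strain differed by more than counting error: the chi-square per degree of freedom over genes with at least 20 counts in a pair of replicates was 1.40 to 2.68 in pairs of WT libraries, 7.40 to 12.2 in pairs of tup1 MATalpha libraries, 4.08 for tup1 MATa replicates 2 and 3, and 21.0 and 28.3 for tup1 MATa replicate 1 against these, which sets it apart.

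Counts were analysed with edgeR 4.0.16 in R 4.3.3. Genes with low counts were removed with filterByExpr by group at its minimum count of 10, leaving 5654 genes tested; libraries were scaled by TMM. All 12 libraries entered 1 quasi-likelihood fit of the 4 group means (robust, 8 residual degrees of freedom), from which 5 contrasts were tested two-sided: tup1 against WT in each mating type, the difference between those effects (the interaction, MATalpha minus MATa), and MATalpha against MATa in WT and in tup1. Adjusted p-values are Benjamini-Hochberg values over all genes tested, with a threshold of 0.05, and every adjusted p given for a gene comes from this test; changes of at least 2-fold among the calls were counted too. Levels are CPM, the usual scaling of counts to a common library total, here with TMM factors, given as mean ± SD over the 3 replicates, and log2 fold changes carry their standard error (SE). For genes with 0 counts in all libraries of 1 group, a fold is given as a lower bound against a floor of 3 counts over the group; with 1 to 3 counts a ratio is given with its exact 95% interval. Both cover counting error only. These genes enter the median of a list by rank.

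Counts were simulated from the mean levels in WT MATa, 1 dispersion per gene for all libraries and the scaled library totals. The test was tried on these counts, with 200 changed genes. For tup1 against WT in MATa (5540 genes) it found 76.1% of genes changed by 0.5 on the log2 scale, 95.5% at 1 and 97.0% at 2, with 4.28% of its calls on unchanged genes. For the interaction (5548 genes) it found 41.8%, 86.6% and 95.5%, with 8.02% of calls on unchanged genes. The simulated tup1 libraries had the same dispersions as the WT ones, and only 200 genes changed. In the real data these shares may therefore differ.

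Before the data were examined, 25 gene lists and 10 single genes (TUP1, CYC8, HO, CDC6, SUC2, FLO11, RNR3, ANB1, STE2 and STE3) were fixed from textbook knowledge. The lists are a-specific, alpha-specific, haploid-specific and pheromone-induced genes; glucose-repressed, hypoxic, DAN/TIR cell wall, Rfx1-regulated DNA damage, flocculation, osmotic, general stress, iron, phosphate and amino acid biosynthesis (Gcn4) genes; M/G1, G1/S and meiotic genes; Tup1-Cyc8 and its DNA-binding partners; respiration, ribosome biogenesis, ribosomal protein, seripauperin (PAU) and mitochondrially encoded genes; genes within 20 kb of a chromosome end; and the marker genes of the strain background. Of the tested genes 27 were in more than 1 list, or 8 with the genes near chromosome ends left out. AFB1 was put among the a-specific genes, but stood higher in MATalpha than in MATa libraries. Lists were tested with camera (limma 3.58.1), a competitive test on log2 CPM, with a preset correlation of 0.01 and adjustment over the lists of a contrast; an estimated correlation and fry were alternatives. In the simulated data camera called the list that was shifted and 0 of 20 random lists. Genes were simulated independently of each other there, so this did not test the preset correlation. In the real lists the estimated correlation reached 0.664, for ribosomal protein genes. Genes named in the text are the single genes, for each contrast the 10 largest rises and 10 largest falls among the calls (groups not overlapping, except for the interaction, and at least 5 CPM in the higher group), and up to 4 called members of each list with the smallest p. FUS1, ARG1, MFA2, STE6, AFB1, ASG7, KSS1, MGA2 and SKO1 are also named in contrasts where this rule does not name them, chosen after their values were seen. Other genes chosen so are said to be so where they are named.

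Alternatives fixed before the data were examined were RLE and upper-quartile scaling, no low-count filter, a filter of 5 CPM in 3 libraries, DESeq2 1.42.0, a fit of only the groups compared, the replicate number as a block, protein-coding genes only, and leaving out each library in turn. The counts of list members without single libraries and under other scalings were added after the data were seen. The deposited table is the only file used here.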

Results

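RNA was counted in 4 W303 yeast strains with 3 replicates each: WT MATa, WT MATalpha, tup1(S649F) MATa and tup1(S649F) MATalpha. Total counts were 8250888, 7722119 and 7102722 in the WT MATa libraries and 9300353, 6718579 and 6339280 in the WT MATalpha libraries. They were 8337346, 6045757 and 7370377 in tup1 MATa and 5657714, 7549523 and 6574420 in tup1 MATalpha, replicates 1 to 3 in order. In a principal component analysis of the 12 libraries, component 1 (72.1% of the variance) separated tup1 from WT, and component 2 (15.3%) separated the MATalpha from the MATa libraries, more widely in tup1 than in WT. Mitochondrial open reading frames took 0.394 ± 0.0111% of the counts in WT MATa and 0.367 ± 0.00322% in WT MATalpha, against 0.459 ± 0.0251% in tup1 MATa and 0.656 ± 0.0481% in tup1 MATalpha (SD, n = 3). Residual ribosomal RNA took 0.822 ± 0.0205%, 0.946 ± 0.0222%, 0.981 ± 0.229% and 1.32 ± 0.189% in the same order.

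TUP1 (YCR084C, R64 chromosome III 260311 to 262452), the mutated gene, rose in tup1 MATa, from 386.8 ± 9.25 to 526 ± 51.9 CPM (SD, n = 3; log2 fold change 0.44 ± 0.08 SE, adjusted p = 0.000119). In MATalpha it stood at 447 ± 12.4 and 479 ± 37.2 CPM, a difference that did not pass the test (0.10, adjusted p = 0.266). As a point mutation leaves the transcript in place, its level does not check the label. The interaction for TUP1 was −0.34 (adjusted p = 0.0283). It lost its call, with adjusted p of 0.0576 to 0.0838, without WT MATa replicate 1 or 2, WT MATalpha replicate 1 or 3, tup1 MATa replicate 2 or tup1 MATalpha replicate 3. CYC8, which encodes the partner of Tup1 in the corepressor, rose in MATa (0.28, adjusted p = 0.00683) and did not pass in MATalpha (−0.14, adjusted p = 0.139). The effects differed between the mating types (interaction −0.42, adjusted p = 0.00957). The CYC8 rise in MATa was not called with upper-quartile scaling (0.18, adjusted p = 0.0689) or without tup1 MATa replicate 2 (adjusted p = 0.0538). In MATalpha CYC8 was called lower with upper-quartile scaling (−0.29, adjusted p = 0.00409) and without tup1 MATalpha replicate 1 (adjusted p = 0.0427) or tup1 MATa replicate 1 (adjusted p = 0.0474).

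The comparison of MATalpha with MATa in WT shows which genes follow mating type when Tup1 is intact. STE2, which encodes the alpha-factor receptor of MATa cells (YFL026W, chromosome VI 82580 to 83875), stood at 613 ± 17.9 CPM in MATa and 5.47 ± 0.376 in MATalpha (SD, n = 3). STE3, the a-factor receptor of MATalpha cells (YKL178C, chromosome XI 113215 to 114627), stood at 1.63 ± 0.556 and 479 ± 22.0 CPM. Of 8 listed a-specific genes 7 were lower in MATalpha, among them the a-factor exporter STE6 (−5.05), the alpha-factor protease BAR1 (−6.63) and the a-factor gene MFA2 (−8.94). The other, AFB1, was higher in MATalpha (4.42). All 4 alpha-specific genes were higher in MATalpha, with log2 fold changes of 8.16 for STE3, 3.97 for the agglutinin SAG1 and 10.64 for the alpha-factor gene MF(ALPHA)2, and a ratio of 10990 (95% interval 3041 to 90710, counting error) for MF(ALPHA)1. HMRA1 (chromosome III 293835 to 294321), whose sequence MATa cells also carry at MAT, had 0 counts in each MATalpha library and was at least 76.6-fold lower there. Apart from AFB1, these genes matched the mating type label of each library.

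In all, 30 genes were higher and 21 lower in WT MATalpha, 0.902% of the 5654 tested, and 8 and 9 of them changed at least 2-fold. The a-specific list was lower (median log2 fold change −6.71, camera adjusted p = 1.62e-34) and the alpha-specific list higher (9.40, adjusted p = 9.47e-32), with the same counts adjusted over the list alone. Respiration genes were slightly lower (2 lower, 19 adjusted over the list alone, median −0.20, adjusted p = 5e-10), and so were glucose-repressed genes (2 lower, 6 adjusted over the list alone, −0.13, adjusted p = 0.00323). They had adjusted p = 0.242 and 0.0552 with an estimated correlation. Camera also called Tup1-Cyc8 and its partners higher (0 called by edgeR, 7 adjusted over the list alone, 8 at an unadjusted p under 0.05, 1 by DESeq2; median 0.21, adjusted p = 2.31e-05). It called iron genes lower (0 called by edgeR, 0 adjusted over the list alone or by DESeq2, 3 at an unadjusted p under 0.05; −0.14, adjusted p = 0.0366). Mitochondrially encoded genes were lower (1 lower, 8 lower and 2 higher adjusted over the list alone, −0.09, adjusted p = 0.0169). Genes near chromosome ends were lower too (3 lower, 8 lower and 1 higher adjusted over the list alone, −0.05, adjusted p = 0.0169). These 4 lists had adjusted p = 0.387, 0.671, 0.387 and 0.585 with an estimated correlation. The haploid-specific and pheromone-induced genes were among 14 lists with 0 members called by edgeR and no camera call. Of their 339 members 42 had an unadjusted p under 0.05, DESeq2 called 2, and adjusted over the list alone 1 hypoxic, 1 DAN/TIR and 1 general stress gene was called. The ribosome biogenesis gene RLP24 and RNR4 were higher, both losing their calls with RLE scaling. Of the phosphate genes PHM6 was higher and PHO11 and PHO89 were lower (1 and 3 adjusted over the list alone). Each of these 5 genes lost its call without single WT libraries, and their 3 lists had no camera call. The count of calls depended on the libraries in the fit. A fit of the 6 WT libraries alone called 520 higher and 571 lower, against 179 and 220 without tup1 MATa replicate 1 and 49 and 43 without tup1 MATa replicate 3. Without tup1 MATa replicate 1, 17 respiration, 6 glucose-repressed and 12 telomere genes were lower, 6 of the Tup1 partners higher, and 7 ribosomal protein genes higher and 16 lower. Leaving out 1 of the 6 WT libraries gave 11 to 16 higher genes, and 11 to 13 lower ones for each but WT MATa replicate 1.

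The comparison of tup1 with WT in MATa cells asks which genes depend on Tup1 there. Stress, hypoxic, DNA damage and glucose-repressed genes rose. RNR3 (YIL066C, chromosome IX 238099 to 240708), a DNA damage-inducible subunit of ribonucleotide reductase, went from 12.5 ± 0.785 to 428 ± 59.0 CPM (SD, n = 3; 5.09 ± 0.11 SE, adjusted p = 1.35e-17). The invertase gene SUC2 (YIL162W, chromosome IX 37385 to 38983) went from 138 ± 4.17 to 612 ± 10.8 CPM (2.15 ± 0.07, adjusted p = 6.06e-15). TIR1 (YER011W, chromosome V 175248 to 176012), a cell wall mannoprotein of anaerobic growth, went from 6.93 ± 0.796 to 434.5 ± 38.3 CPM (5.97 ± 0.13, adjusted p = 1.56e-17), and ANB1, the hypoxic form of a translation factor, from 4.996 ± 0.611 to 234 ± 43.3 CPM (5.55 ± 0.16, adjusted p = 1.04e-13). FLO11, a cell surface flocculin, rose by 3.62 ± 0.24 on the log2 scale (adjusted p = 1.53e-08). Across the genome 1395 genes were higher and 947 lower, 41.4% of those tested, but of the genes changed at least 2-fold 457 were higher and 33 lower.

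All 6 DAN/TIR genes rose (median 3.98, camera adjusted p = 7.17e-08). So did all 5 flocculation genes (3.62, adjusted p = 1.33e-07), where FLO9 rose most (6.81) but shares reads with FLO1 and FLO5. Of 6 Rfx1-regulated DNA damage genes 5 rose, with RNR2 at 2.50, RNR4 at 2.01 and HUG1 at 6.17 beside RNR3 (median 2.26, adjusted p = 4.06e-06). Glucose-repressed genes rose in 25 of 30 cases and fell in 0 (27 and 0 adjusted over the list alone, median 1.93, adjusted p = 2.32e-15). Among them were the activator ADR1 (2.49) and the transporter HXT7 (2.97, shared with HXT6). Of 14 hypoxic genes 12 rose and 0 fell (1.21, adjusted p = 7.17e-08), for example the sterol transporter PDR11 (3.16) and the heme synthesis gene HEM13 (1.59). Osmotic genes rose in 8 of 11 cases (9 adjusted over the list alone, 1.48, adjusted p = 9.07e-07), with GRE2 at 1.82 and the glycerol synthesis gene GPD1 at 1.56. All 24 general stress genes rose (1.84, adjusted p = 2.32e-20). They included the cell wall gene SPI1 (4.88), glycogen phosphorylase GPH1 (2.999) and the chaperone HSP26 (4.38), and the list had adjusted p = 0.0511 with an estimated correlation. For each list given with a single count, in this and the other comparisons, it was the same when adjusted over the list alone.

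Several lists moved less. Of 19 genes of Tup1-Cyc8 and its DNA-binding partners 17 rose and 0 fell (18 and 0 adjusted over the list alone, median 0.88, adjusted p = 1.33e-07), with CIN5 at 2.04, YAP6 at 2.15 and NRG1 at 2.42. The partners had adjusted p = 0.187 with an estimated correlation. Seripauperin genes, whose copies share reads, rose in 8 of 11 cases (9 adjusted over the list alone, 1.65, adjusted p = 0.00532). Seripauperins had adjusted p = 0.0958 with an estimated correlation. Iron genes rose in 15 of 25 cases and fell in 0 (0.43, adjusted p = 3.33e-05), for example FIT2, a cell wall protein that retains siderophores, by 4.68. Iron genes had adjusted p = 0.391 with an estimated correlation. Of 22 M/G1 genes 15 rose and 1 fell (15 and 2 adjusted over the list alone, 0.31, adjusted p = 0.000385), or 10 and 4 with upper-quartile scaling, led by the cell wall gene PIR3 (5.11). M/G1 genes had adjusted p = 0.0819 with an estimated correlation. HO, the mating type switching endonuclease (YDL227C, chromosome IV 46271 to 48031), rose from 62.9 ± 3.31 to 118 ± 6.17 CPM (SD, n = 3; 0.91 ± 0.09 SE, adjusted p = 4.74e-08). The replication licensing gene CDC6 rose by 0.32 (adjusted p = 0.0105). That call was lost with upper-quartile scaling (0.21, adjusted p = 0.0623) and without WT MATa replicate 3 (adjusted p = 0.057). Of 18 meiotic genes 8 rose and 0 fell (0.42, adjusted p = 0.0359), with the spore wall gene DIT1 at 3.62. Meiotic genes had adjusted p = 0.306 with an estimated correlation. Of 33 respiration genes 20 rose and 0 fell (21 and 0 adjusted over the list alone, 0.24, adjusted p = 0.000718), but 13 rose and 2 fell with upper-quartile scaling. Respiration genes had adjusted p = 0.391 with an estimated correlation. Of 153 genes within 20 kb of a chromosome end 65 rose and 27 fell (67 and 33 adjusted over the list alone, 0.22, adjusted p = 0.0119). These genes had adjusted p = 0.402 with an estimated correlation. Of them 43 (28.1%) rose at least 2-fold, against 414 (7.53%) of the other 5501 (two-sided Fisher's exact p = 8.47e-14, with genes not independent).

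Part of the amino acid, ribosomal protein and ribosome biogenesis genes fell. The fall was largest for ARG1, an arginine synthesis gene (YOL058W, chromosome XV 219211 to 220473), which went from 51.8 ± 2.26 to 11.5 ± 1.66 CPM (SD, n = 3; −2.16 ± 0.16 SE, adjusted p = 5.04e-09). SAM2, which makes S-adenosylmethionine, went from 452 ± 11.99 to 124 ± 12.9 CPM (−1.87 ± 0.07, adjusted p = 7.2e-14). COS8, a gene near a telomere with similar copies, fell by 2.05 on the log2 scale. Of 32 Gcn4 targets 20 fell and 7 rose (median −0.31, adjusted p = 5.38e-05), with LEU1 at −1.24 but HIS5 at 1.17 and LYS1 at 0.68; adjusted p = 0.407 with an estimated correlation. Of 137 ribosomal protein genes 63 fell and 0 rose (69 adjusted over the list alone, −0.25, adjusted p = 1.39e-10), and of 30 ribosome biogenesis genes 16 fell and 0 rose (−0.17, adjusted p = 4.09e-05), such as ERB1 (−0.31) and RRP5 (−0.35). These had adjusted p = 0.452 and 0.251 with an estimated correlation. The ribosomal protein count was 102 lower and 2 higher without tup1 MATa replicate 1, the library that stands apart, and 101 lower with upper-quartile scaling.

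Mating genes as groups did not pass in MATa. Of the a-specific genes MFA2 rose (0.86) and BAR1 (−0.88) and STE6 (−0.28) fell, while STE2 did not pass (−0.07, adjusted p = 0.664). Their median was 0.06, or −0.05 with upper-quartile scaling, and their mean −0.01, with camera pointing down (adjusted p = 0.654). Of the 4 alpha-specific genes 0 were called by edgeR, at an unadjusted p under 0.05 or by DESeq2. Their median was −0.30 and their mean 0.18, with camera pointing down (adjusted p = 0.679) and STE3 at −0.79 (adjusted p = 0.131). Of 11 haploid-specific genes HO and RME1 rose and AXL1 and GPA1 fell (median −0.02, mean 0.10, camera up, adjusted p = 0.846). GPA1 lost its call without WT MATa replicate 1, 2 or 3, WT MATalpha replicate 2, tup1 MATa replicate 1 or 2 or tup1 MATalpha replicate 3 (adjusted p up to 0.15). Of 22 pheromone-induced genes 7 rose and 3 fell, or 4 and 4 with upper-quartile scaling (median −0.13, adjusted p = 0.848). AFR1, needed for mating projections, rose (1.37) and the fusion gene FUS1 fell (−1.91 ± 0.39 SE, adjusted p = 0.00174). Phosphate genes rose in 4 and fell in 5 of 15 cases (4 and 7 adjusted over the list alone). Their median was −0.09 and their mean 0.28, with camera pointing down (adjusted p = 0.654). G1/S genes rose in 7 and fell in 5 of 20 cases (median 0.02, or −0.09 with upper-quartile scaling, adjusted p = 0.829). Mitochondrially encoded genes rose in 4 of 19 cases (2 adjusted over the list alone, 0.14, adjusted p = 0.538). Of 6 strain marker genes TRP1 rose and LEU2 fell (median 0.14, mean −0.03, camera down, adjusted p = 0.746). TRP1 lost its call with upper-quartile scaling, with DESeq2, in a fit of the MATa libraries alone and without WT MATa replicate 1 or 3 or tup1 MATa replicate 1 (adjusted p up to 0.153).

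Numbers of lower genes depended on scaling. Upper-quartile factors moved the median of all genes in MATa from −0.01 to −0.12, lower calls from 947 to 1778 and the share of higher genes among the calls from 59.6% to 38.5%. Without WT MATa replicate 1 or 3 there were 617 and 619 lower genes.

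The same comparison in MATalpha cells gave 1810 higher and 1755 lower genes, 63.1% of those tested, and of those changed at least 2-fold 727 were higher and 31 lower. The rises included a-specific genes, which WT MATalpha cells keep low. STE2 went from 5.47 ± 0.376 to 575 ± 116 CPM (SD, n = 3; 6.70 ± 0.16 SE, adjusted p = 4.04e-16), beside 585 ± 64.2 CPM in tup1 MATa. Of 8 a-specific genes 7 rose and 0 fell (median 6.96, camera adjusted p = 1.12e-07): STE6 by 4.21, BAR1 by 6.89, MFA2 by 10.00, the agglutinin subunit AGA2 by 9.87 and MFA1 by a ratio of 876 (95% interval 299 to 4252, counting error), with ASG7 also higher. AFB1, which stood higher in MATalpha than in MATa of WT, was not called. Without AFB1 the list had a median of 7.03 (camera adjusted p = 1.08e-08). SAG1 went from 667 ± 60.0 to 5295 ± 1068 CPM (2.99 ± 0.12, adjusted p = 9.36e-14). STE3 rose from 479 ± 22.0 to 797 ± 110.4 CPM (0.74 ± 0.09, adjusted p = 9.15e-07) and MF(ALPHA)2 by 1.32, so that 3 of 4 alpha-specific genes rose (median 1.03), although the list did not pass (adjusted p = 0.0611).

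Pheromone-induced genes rose in 21 of 22 cases in MATalpha, all but KSS1 (median 2.36, adjusted p = 9.39e-12). The list had adjusted p = 0.0805 with an estimated correlation. FUS1 (YCL027W, chromosome III 71803 to 73341), needed for fusion of mating cells, went from 15.6 ± 4.02 to 165 ± 43.0 CPM (SD, n = 3; 3.38 ± 0.21 SE, adjusted p = 1.84e-08). The membrane protein gene PRM2 rose by 6.67 on the log2 scale. FIG1, a membrane protein of mating cells, reached 187 ± 44.4 CPM. Haploid-specific genes rose in 5 of 11 cases and fell in 0, or 3 and 2 with upper-quartile scaling (median 0.27, adjusted p = 0.0851). They included the mating kinase FUS3 (1.29) and the cell cycle inhibitor FAR1 (1.11). HO did not pass in MATalpha (67.3 ± 4.40 and 64.2 ± 9.77 CPM, −0.07, adjusted p = 0.545), though it was called lower with upper-quartile scaling (−0.22, adjusted p = 0.0442). CDC6 did not pass either (−0.02, adjusted p = 0.87).

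**Figure D1:**
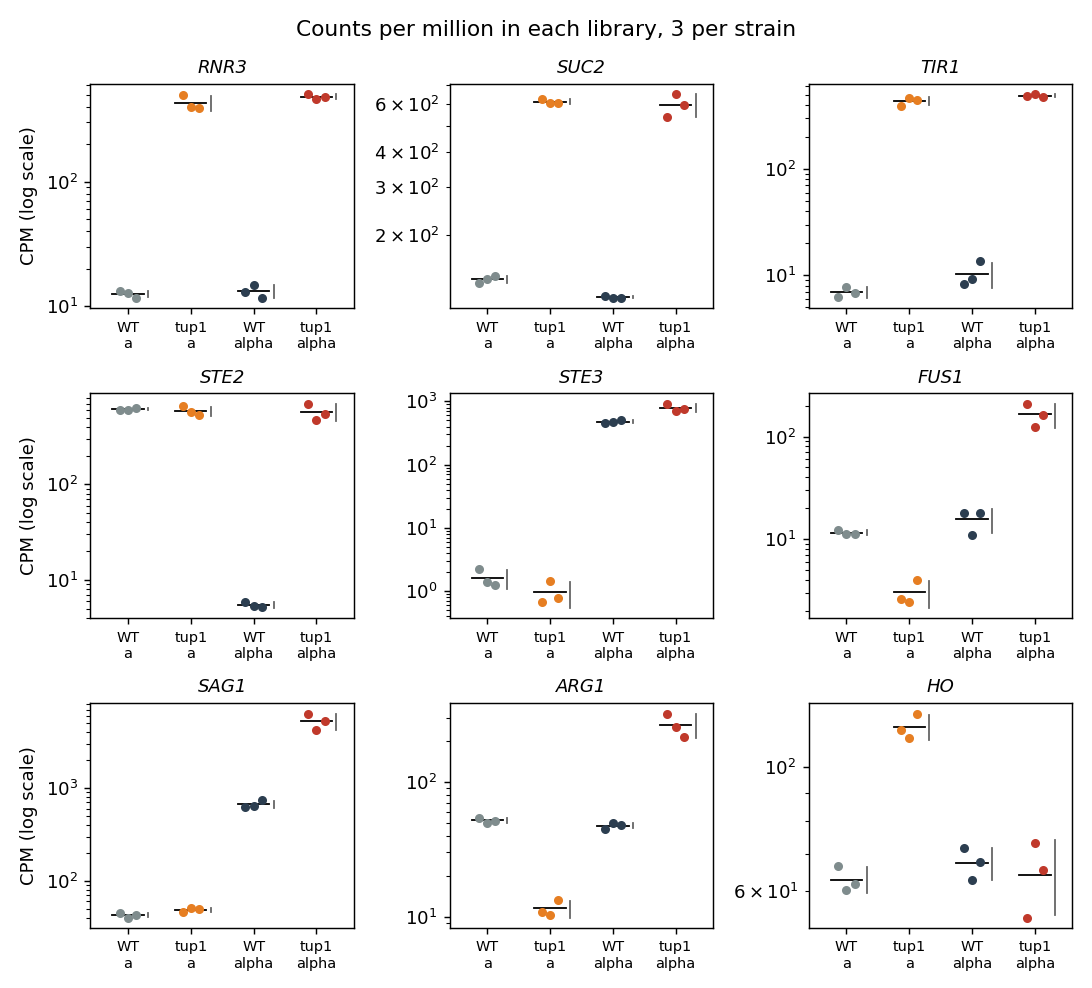
Levels of 9 genes (CPM, log axis) in each library of the 4 strains, with points for libraries, black lines for group means and grey bars for SD (n = 3). RNR3, SUC2 and TIR1 stand higher in tup1 of both mating types, whereas STE2, FUS1 and SAG1 rise in tup1 MATalpha and ARG1 goes opposite ways in MATa and MATalpha.

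The classes that rose in MATa rose in MATalpha as well. RNR3 reached 483.5 ± 22.3 from 13.2 ± 1.57 CPM (SD, n = 3; 5.19 ± 0.11 SE, adjusted p = 4.94e-18), and SUC2 595 ± 57.3 from 119 ± 0.817 CPM (2.32 ± 0.07, adjusted p = 1.26e-15). ANB1 reached 248 ± 17.1 from 6.01 ± 1.40 CPM (5.40 ± 0.16, adjusted p = 6.02e-14). All 6 DAN/TIR genes rose (median 4.15, camera adjusted p = 1.63e-05), with TIR1 at 5.60. All 5 flocculation genes rose (2.88, adjusted p = 1.86e-05), with FLO11 at 2.88 and FLO10 at 2.82, as did 5 of 6 Rfx1-regulated genes (2.31, adjusted p = 0.000258), with 1 lower under upper-quartile scaling. Glucose-repressed genes rose in 29 of 30 cases (2.34, adjusted p = 1.37e-12), with ADR1 at 2.71 and the maltase MAL12, which shares reads with MAL32, at 8.07. Hypoxic genes rose in 12 and fell in 1 of 14 cases (1.18, adjusted p = 3.47e-05), the fall being that of the membrane regulator MGA2. Osmotic genes rose in 9 and fell in 1 of 11 cases (1.47, adjusted p = 1.63e-05), the fall being that of the repressor SKO1. All 24 general stress genes rose (2.26, adjusted p = 5.08e-14), with GPH1 at 3.95. General stress genes had adjusted p = 0.0805 with an estimated correlation. Seripauperin genes rose in 11 of 11 cases (2.71, adjusted p = 0.000177).

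Meiotic genes rose in 13 and fell in 1 of 18 cases in MATalpha (median 1.47, adjusted p = 0.000978), with the meiotic activator IME1 at 2.94. Meiosis had adjusted p = 0.0859 with an estimated correlation. Respiration genes rose in 30 of 33 cases (0.57, adjusted p = 4.6e-09), such as the citric acid cycle genes CIT1 (1.37) and IDH2 (1.48). Mitochondrially encoded genes rose in 12 of 19 (0.70, adjusted p = 0.00079), with COX1 at 1.26. Both lists had adjusted p = 0.0901 with an estimated correlation. The mitochondrial share of counts stood at 0.656% there against 0.367% in WT MATalpha. Iron genes rose in 15 and fell in 1 of 25 cases (0.41, adjusted p = 0.00631). Tup1-Cyc8 and its partners rose in 11 and fell in 2 of 19 (0.35, adjusted p = 0.0209), with NRG1 at 2.63. With upper-quartile scaling the counts were 11 and 3 for iron genes and 9 and 4 for the partners. Each of these lists had adjusted p = 0.458 with an estimated correlation. Genes near chromosome ends rose in 86 and fell in 26 of 153 cases (86 and 27 adjusted over the list alone, 0.56, adjusted p = 1.63e-05). The telomere list had adjusted p = 0.11 with an estimated correlation. Of its genes 64 (41.8%) rose at least 2-fold, against 663 (12.1%) of the others (two-sided Fisher's exact p = 1.13e-19). Gcn4 targets rose in 25 and fell in 3 of 32 cases (0.74, adjusted p = 8.49e-07), and had adjusted p = 0.26 with an estimated correlation. ARG1 went from 47.3 ± 2.10 to 264 ± 53.1 CPM (SD, n = 3; 2.48 ± 0.12 SE, adjusted p = 8.96e-12).

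Ribosomal protein genes fell in 102 of 137 cases in MATalpha and rose in 0 (median −0.41, adjusted p = 2.67e-11). Ribosome biogenesis genes fell in 29 of 30 (−0.49, adjusted p = 5.76e-10), with ERB1 at −0.70 and RRP5 at −0.78. They had adjusted p = 0.396 and 0.0751 with an estimated correlation. The largest fall was that of DIP5, a dicarboxylic amino acid permease (YPL265W, chromosome XVI 41043 to 42869), from 318 ± 15.1 to 26.0 ± 3.19 CPM (SD, n = 3; −3.61 ± 0.08 SE, adjusted p = 1.08e-17). SAM2 fell by 1.70 on the log2 scale, and UTR2, a chitin transglycosylase of the cell wall, by 1.69. M/G1 genes rose in 10 and fell in 7 of 22 cases (0.09, adjusted p = 0.149), or 9 and 9 with a median of −0.06 under upper-quartile scaling. Here PIR3 stood at 6.01 and the cell wall gene PST1 at 1.90. G1/S genes rose in 7 and fell in 6 of 20 cases, or 6 and 9 with upper-quartile scaling (median −0.06, mean 0.03, camera down, adjusted p = 0.82). Phosphate genes rose in 5 and fell in 8 of 15 (median −0.18, mean 0.24, camera down, adjusted p = 0.562). Strain marker genes rose in 2 and fell in 2 of 6 (median 0.12, or −0.03 with upper-quartile scaling, adjusted p = 0.979). Upper-quartile factors moved the median of all genes from −0.03 to −0.18 and the share of higher genes among the calls from 50.8% to 37.5%.

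**Figure D2:**
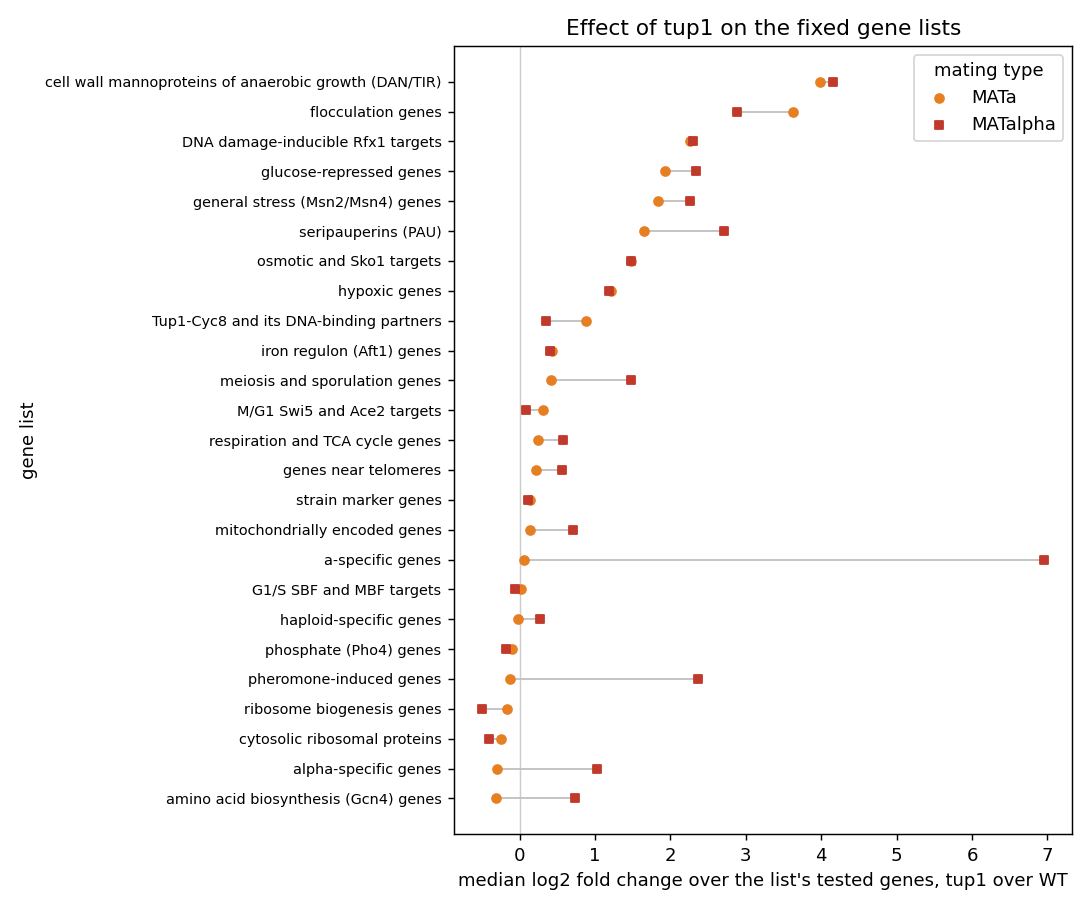
Median log2 fold change of tup1 against WT for each gene list in MATa (orange circles) and MATalpha (red squares). The a-specific list stands at 0.06 in MATa (−0.05 with upper-quartile scaling) and 6.96 in MATalpha, and the Gcn4 list at −0.31 and 0.74, while the DAN/TIR list stands at 3.98 and 4.15.

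The effects of tup1 in the mating types were compared to see how much of the response does not depend on mating type. They rest on separate libraries, but on 1 fit with a shared spread per gene, filter and scaling. Higher in both were 1189 genes, where 446.6 would be by chance if calls were independent, and lower in both 695, where 293.9 would be. As the spread is shared, calls are not independent and the overlap by chance may be larger. Of genes changed at least 2-fold, 422 were higher in both, such as RNR3, SUC2 and TIR1, and 8 lower in both. The log2 fold changes had a Pearson r of 0.773 and a Spearman rho of 0.70 across the 5654 genes, which are not independent replicates. Called in opposite directions were 76 genes, 51 of them lower in MATa and higher in MATalpha. Chosen from these after their values were seen, the arginine and histidine synthesis genes ARG3 (−1.07 and 1.48) and HIS4 (−0.76 and 1.57) and the pheromone response regulator SST2 (−0.79 and 1.38) fell in MATa and rose in MATalpha, and the daughter cell wall gene EGT2 rose in MATa (0.31) and fell in MATalpha (−0.38). The rise of EGT2 was not called with upper-quartile scaling (adjusted p = 0.0516) or without tup1 MATa replicate 2 (adjusted p = 0.065). The count lower in both was 445 without WT MATa replicate 1 and 458 without replicate 3.

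**Figure D3:**
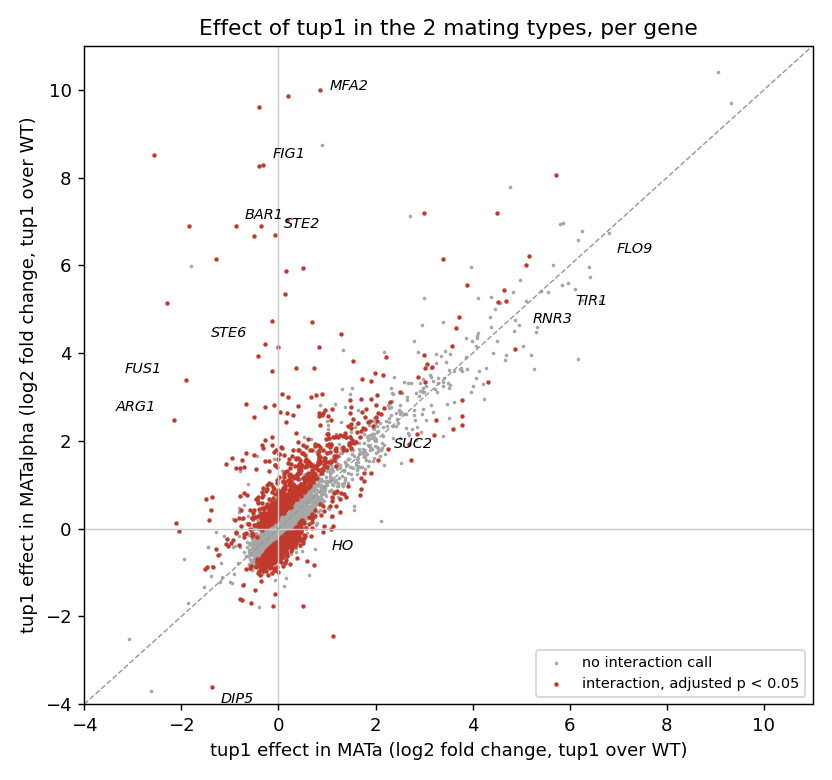
Log2 fold change of tup1 against WT in MATa (horizontal axis) and in MATalpha (vertical axis) for the 5654 genes tested, with a dashed line of equal change and red points for genes whose effects differed (interaction adjusted p under 0.05). STE2, MFA2, BAR1, STE6, FIG1 and FUS1 lie above the line, and DIP5 and HO below it.

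The interaction tests directly whether tup1 acts differently in MATalpha and in MATa. Genes with the higher effect in MATalpha included genes of mating, the pheromone response and amino acid synthesis. Of their 5 lists the a-specific one alone kept its call with an estimated correlation (adjusted p = 0.0201, and 0.0539 to 0.479 for the others). STE2 differed by 6.76 ± 0.20 SE (adjusted p = 1.42e-13, n = 3 per group), FUS1 by 5.29 ± 0.42 (adjusted p = 3.65e-06), SAG1 by 2.79 ± 0.18 (adjusted p = 1.93e-09) and ARG1 by 4.64 ± 0.19 (adjusted p = 3.56e-11). DIP5 fell further in MATalpha (−2.24 ± 0.11, adjusted p = 1.94e-11), HO rose in MATa but not in MATalpha (−0.97 ± 0.13, adjusted p = 1.79e-05), and COS8 fell in MATa but not in MATalpha (2.01 ± 0.14, adjusted p = 7.98e-09). SUC2, RNR3, ANB1 and FLO11 were not called, with adjusted p of 0.213, 0.687, 0.746 and 0.167. In all, 701 genes had a higher and 648 a lower effect in MATalpha, 23.9% of those tested.

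Of 8 a-specific genes 7 had a higher effect in MATalpha and 0 a lower one (median 7.31, adjusted p = 7.79e-18). Of 4 alpha-specific genes SAG1 and STE3 did (3 adjusted over the list alone, list median 1.82, camera adjusted p = 0.00306). The list median of the tup1 effect in MATalpha itself was 1.03. In WT MATa the gene MF(ALPHA)1 had 2 counts over the group. STE3 had 19, 11 and 9 counts in WT MATa and 5, 9 and 6 in tup1 MATa, so its interaction rests partly on few counts. STE3 lost its call without WT MATa replicate 1 (adjusted p = 0.0811) or tup1 MATa replicate 1 (adjusted p = 0.0533), and the list had adjusted p = 0.0907 with an estimated correlation. All 22 pheromone-induced genes had a higher effect in MATalpha (2.25, adjusted p = 2.7e-27), with PRM1 at 7.26, FIG2 at 5.43, PRM5 at 1.39 and the motor regulator CIK1 at 1.51. The pheromone list had adjusted p = 0.0539 with an estimated correlation. Of 32 Gcn4 targets 30 did (0.81, adjusted p = 2.26e-27), among them ARG4 (2.38) and the serine synthesis gene SER3 (2.05). This list had adjusted p = 0.0766 with an estimated correlation. Haploid-specific genes had 4 higher and 1 lower (5 and 1 adjusted over the list alone, 0.25, adjusted p = 0.0465), with FUS3 at 1.15 and FAR1 at 1.14. Haploid genes had adjusted p = 0.479 with an estimated correlation. Respiration genes had 25 higher (27 adjusted over the list alone, 0.42, adjusted p = 4.28e-11), with CIT1 at 0.93. Mitochondrially encoded genes had 9 higher (11 adjusted over the list alone, 0.50, adjusted p = 4.24e-05), with COX1 at 1.02. Either list had adjusted p = 0.0907 with an estimated correlation. The mitochondrial share of counts was 0.459% in tup1 MATa and 0.656% in tup1 MATalpha. Genes near chromosome ends had 42 higher and 11 lower (45 and 12 adjusted over the list alone, 0.36, adjusted p = 4.24e-05). Seripauperins had 1 higher, PAU17 (list median 0.97, camera adjusted p = 0.00535), and glucose-repressed genes 5 higher and 1 lower (list median 0.31, camera adjusted p = 0.00535). Meiotic genes had 5 and 1 (6 and 1 adjusted over the list alone, 5 and 0 with DESeq2, 0.60, adjusted p = 0.0271), with IME1 at 1.46. The last 4 lists had adjusted p = 0.177, 0.0907, 0.0766 and 0.246 with an estimated correlation.

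Ribosome biogenesis genes had lower effects in MATalpha (16 lower and 0 higher, 21 and 0 adjusted over the list alone, median −0.33, adjusted p = 3.74e-09), with NOC2 at −0.52 and YTM1 at −0.49. So had ribosomal protein genes (13 lower, 7 adjusted over the list alone, −0.12, adjusted p = 0.00306). Tup1-Cyc8 and its partners followed (6 lower, 8 adjusted over the list alone, −0.31, adjusted p = 0.00595), including the repressor MIG3 (−0.88) and the mating type cofactor MCM1 (−0.59). In this order the 3 lists had adjusted p = 0.0907, 0.798 and 0.525 with an estimated correlation. The remaining 11 lists did not pass. Of hypoxic genes PDR11 was higher (0.52; list adjusted p = 0.882), and of flocculation genes FLO10 (0.81; 0.428). DAN/TIR genes had 0 called by edgeR or DESeq2 and 1 at an unadjusted p under 0.05 (list adjusted p = 0.949), and Rfx1-regulated genes 0 by any of these (0.87). Osmotic genes had 4 higher (5 adjusted over the list alone, list adjusted p = 0.0513), with HAL1 at 1.56, and general stress genes 9 higher and 2 lower (0.153). Iron genes had 1 higher and 2 lower (1 and 1 adjusted over the list alone, list adjusted p = 0.298) and M/G1 genes 6 and 6 (7 and 9 adjusted over the list alone, 0.631). G1/S genes had 1 and 1 (0 and 1 adjusted over the list alone, list adjusted p = 0.428), phosphate genes 3 and 5 (4 and 6 adjusted over the list alone, 0.455), and strain marker genes 2 higher (0.455). With upper-quartile scaling the higher and lower counts were 1 and 1 for hypoxic, 4 and 1 for osmotic, 4 and 9 for M/G1 and 0 and 2 for G1/S genes, the last 1 and 2 with DESeq2. Without tup1 MATa replicate 1 there were 998 lower genes in place of 648, with 18 ribosomal protein genes higher and 17 lower and 13 of the partners lower. The ribosomal protein count was 8 without tup1 MATalpha replicate 1 and 21 with upper-quartile scaling, and without tup1 MATalpha replicate 2 there were 10 iron genes lower and 9 glucose-repressed genes higher.

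The comparison of MATalpha with MATa in tup1 shows what is left of the mating type difference in the mutant. STE2 did not differ (575 ± 116 and 585 ± 64.2 CPM, SD, n = 3; −0.03 ± 0.11 SE, adjusted p = 0.88), nor did MFA2 (0.20, adjusted p = 0.185), which was called higher without tup1 MATalpha replicate 2 (0.33, adjusted p = 0.0108). STE3 remained at 0.978 ± 0.430 CPM in MATa and 797 ± 110.4 CPM in MATalpha (9.69 ± 0.17, adjusted p = 3.18e-18). HMRA1 had 0 counts in each tup1 MATalpha library and was at least 58.0-fold lower than in tup1 MATa. In all 1006 genes were higher and 975 lower in MATalpha, 35.0% of those tested, and 192 and 19 of them at least 2-fold. A fit of the 6 tup1 libraries alone called 787 higher and 538 lower, and shared 1322 of the 1981 calls. The main fit takes 1 spread per gene from all libraries, and tup1 libraries scattered more than WT ones. The p-values of this comparison may therefore be too small.

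Alpha-specific genes were higher in 4 of 4 cases (median 10.45, camera adjusted p = 1.54e-11). The a-specific list was higher rather than lower, with 5 higher and STE6 lower at −0.57 (list median 1.39, camera adjusted p = 0.00155). AFB1 is 1 of the 5 (4.20) and was higher in MATalpha of WT too (4.42); the other 7 genes had 4 higher, a median of 1.14 and adjusted p = 0.0303. BAR1 stood at 1.14 and AGA2 at 2.59, and the list had adjusted p = 0.234 with an estimated correlation. All 22 pheromone-induced genes were higher (2.32, adjusted p = 5.08e-27), where PRM6 was at least 151-fold higher and FUS1 stood at 5.73. Of 11 haploid-specific genes 6 were higher, with HO lower (list median 0.28, camera adjusted p = 0.0125). Of the Gcn4 targets 30 were higher (0.74, adjusted p = 5.08e-27), for instance ARG4 at 2.36. The last 3 lists had adjusted p = 0.0553, 0.306 and 0.108 with an estimated correlation. Respiration genes were higher (19 higher, 21 adjusted over the list alone, 0.26, adjusted p = 1.06e-06), with IDH2 at 0.61. Mitochondrially encoded genes were higher (9, 10 adjusted over the list alone, 0.44, adjusted p = 0.000189), and seripauperins too (6, 7 adjusted over the list alone, 0.65, adjusted p = 0.0097). So were osmotic genes (5, or 5 and 1 lower adjusted over the list alone and 4 and 1 with upper-quartile scaling, 0.20, adjusted p = 0.0377). Meiotic genes had 6 higher and 1 lower (7 and 1 adjusted over the list alone, 0.33, adjusted p = 0.0399). Genes near chromosome ends had 54 higher and 17 lower (59 and 18 adjusted over the list alone, 0.23, adjusted p = 0.000731). From respiration onward the 6 lists had adjusted p = 0.234, 0.162, 0.162, 0.234, 0.295 and 0.271 with an estimated correlation.

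Ribosome biogenesis genes were lower in tup1 MATalpha than in tup1 MATa (20 lower, 22 adjusted over the list alone, median −0.26, adjusted p = 2.47e-08). Ribosomal protein genes were lower (17 lower, 2 adjusted over the list alone, −0.15, adjusted p = 0.000396), and so were iron genes (6 lower and 1 higher, −0.12, adjusted p = 0.0172). Among the latter were the iron permease FTR1 (−0.75) and the ferroxidase FET3 (−0.47). FET3 lost its call without tup1 MATa replicate 1 (adjusted p = 0.0917) and in the tup1 libraries alone (adjusted p = 0.0617). These 3 lists had adjusted p = 0.162, 0.687 and 0.605 with an estimated correlation. The ribosomal protein count was 6 higher and 15 lower without tup1 MATa replicate 1, 4 lower without tup1 MATalpha replicate 1 and 29 lower with upper-quartile scaling, and the iron count rose to 15 without tup1 MATalpha replicate 2. The other 11 lists did not pass in this comparison. Glucose-repressed genes had 11 higher and 3 lower (adjusted p = 0.0996), general stress genes 8 and 4 (8 and 5 adjusted over the list alone), and Tup1-Cyc8 and its partners 3 and 5. M/G1 genes had 8 higher and 11 lower (median −0.13, mean 0.03, camera down) and G1/S genes 3 and 6 (5 and 6 adjusted over the list alone, 4 and 5 with RLE scaling, median −0.03, mean 0.002, camera down). Phosphate genes had 3 higher and 8 lower (adjusted p = 0.0964). Without tup1 MATa replicate 1 there were 8 stress genes and 8 of the partners lower, and without tup1 MATalpha replicate 1 there were 7 M/G1 and 5 phosphate genes lower.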

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

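The tests of an admixture of MATa RNA were chosen only after the results were seen; the other tests in this part were chosen before their results were seen.

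The effect of tup1 differed between the mating types, by the test of the interaction, for 701 genes with a higher and 648 with a lower effect in MATalpha. Of the genes chosen beforehand, TUP1 (−0.343), CYC8 (−0.418) and HO (−0.974) had lower effects in MATalpha on the log2 scale, and STE2 (6.764) and STE3 (adjusted p = 0.0119) higher ones. The largest higher effects were those of PRM6 (adjusted p = 0.0074), MFA1 (7.64e-10), AGA2 (1.55e-08), MFA2 (5.71e-13), FIG1 (0.0023), PRM3 (5.07e-06), BAR1 (7.763 on the log2 scale) and PRM1 (7.263), and those of the transfer RNA genes tQ(UUG)D2 (adjusted p = 0.000828) and tA(AGC)P (0.000132), whose reads cannot be placed with certainty. The largest lower effects were those of DIP5 (−2.238), tP(AGG)C (−1.56), HXT5 (−1.418), BSC1 (−1.325), PRM7 (−1.207), SET6 (−1.18), UTR2 (−1.122), YNL146W (−1.104), YEL067C (−1.078) and YDL129W (−1.063), of which SET6 and YEL067C overlap another gene. HXT5 lost its call, with adjusted p up to 0.097, without WT MATa replicate 1, 2 or 3, WT MATalpha replicate 1 or 3, tup1 MATa replicate 2 or 3 or tup1 MATalpha replicate 2. SET6 lost it without WT MATa replicate 3 (adjusted p = 0.0553) or WT MATalpha replicate 1 (adjusted p = 0.104).

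Among gene lists, the median interaction was higher for a-specific (7.306), alpha-specific (1.824), haploid-specific (0.254), pheromone-induced (2.248), glucose-repressed (0.314), Gcn4 (0.81), meiotic (0.598), respiration (0.421), seripauperin (0.97), mitochondrially encoded (0.503) and telomere genes (0.361). It was lower for Tup1-Cyc8 and its partners (−0.314), ribosome biogenesis genes (−0.331) and ribosomal protein genes (−0.122). Of these 14 lists the a-specific one alone kept its call with an estimated correlation (adjusted p = 0.0201), and the others had 0.0539 to 0.798. Of 200 distinct regroupings of the mating type labels within WT and within tup1, 100 were used: the real one, and others drawn at random from the rest. The real one alone called as many genes, 1349 against at most 935. The 7 drawn regroupings that kept the tup1 libraries in their real groups called 775 to 935 genes and the others at most 16. Regroupings that put MATa and MATalpha libraries into 1 group widen the spread within it, which can lower the calls. Their counts therefore do not exclude chance for the interaction. For the other comparisons, 3 libraries against 3 make 10 splits, too few for a share under 0.05. The real values were 2342 genes for tup1 in MATa, 3565 in MATalpha, 51 for mating type in WT and 1981 in tup1. The highest of the other splits was 0 in each, but these splits mix the compared groups in the same way.

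High a-specific and pheromone-induced genes in tup1 MATalpha libraries could come from MATa cells or RNA mixed into them. HMRA1, counted in MATa libraries, had 0 counts in tup1 MATalpha against 199 in tup1 MATa, which limits it to 1.66% of its tup1 MATa level, while the 7 a-specific genes stood at a median of 220.1%. The pheromone-induced genes stood at a median of 4.653 times the higher of their WT MATalpha and tup1 MATa levels, and 22 of 22 stood above it, which no mixture of RNA from those samples gives. This comparison cannot decide on MATa cells within the cultures, as cells grown together may change each other's levels. For such cells only the HMRA1 limit counts. Whether cells held in G1 by their own response account for the pheromone genes stays open: the G2/M genes of the CLB2 cluster had a median interaction of −0.082, and 40.49% of random lists matched on expression lay as low. A loss of repression of a-specific genes in MATalpha cells that then respond to their own alpha-factor is a candidate biological explanation, as a hypothesis, and was not tested apart from the difference between strains.

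Gcn4 targets, lower in tup1 MATa and higher in tup1 MATalpha, might reflect scaling or a gained chromosome. With an estimated correlation the list was called in neither (adjusted p = 0.407 and 0.26) nor in the interaction (adjusted p = 0.0766). Their median interaction was 0.769 with upper-quartile and 0.828 with RLE factors. Such factors move all genes about alike. The median interaction of all genes was −0.032 with TMM, −0.076 with upper-quartile and −0.013 with RLE factors. These sets differ too little for the change of factors to decide on scaling. With TMM the Gcn4 list stood at 0.81, where 30 of 32 genes had a higher effect in MATalpha and 0 a lower one. A factor common to all genes of a library cannot set a list apart from the other genes. This argues against scaling as the cause of the gap between the Gcn4 list and the other genes. No nuclear chromosome had a median interaction beyond that of chromosome V (−0.075), which argues against a whole chromosome gained in 1 strain. Each group is 1 strain, so another difference between the tup1 strains, or between the days of their cultures, cannot be told apart from an effect of mating type.

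The tup1 libraries scattered more than the WT libraries: the median chi-square per degree of freedom of replicate pairs was 10.23 in tup1 and 2.093 in WT, a ratio of 4.887. Thinning all libraries to the lowest total left a ratio of 4.844, and leaving out the 100 most abundant genes 3.811, which argues against depth and a few abundant genes as the whole cause. The ratio of within-group variances was 2.552 before and 2.51 after removal of trends with GC content and gene length. A difference in the handling or growth of the tup1 cultures, and an effect of the mutation itself, stay open, as the labels give no batch.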

How the results depend on the processing

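The list counts under other scalings and without single libraries, and the a-specific list without AFB1, were chosen after the data were seen; the other alternatives were not.

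The numbers of genes that rose or fell with tup1, and of genes shared between the mating types, kept within 1.5 times their value with RLE scaling, no low-count filter, a filter of 5 CPM, DESeq2, the replicate block and protein-coding genes only. DESeq2 shared 2116 of the 2342 calls for tup1 in MATa, 3349 of 3565 in MATalpha, 1166 of 1349 for the interaction, 50 of 51 for mating type in WT and 1745 of 1981 in tup1. With upper-quartile scaling 1778 genes were lower with tup1 in MATa, in place of 947, as these factors move all genes down. A fit of only the groups compared gave 538 lower genes for mating type in tup1 in place of 975. For mating type in WT it gave 520 higher and 571 lower in place of 30 and 21, among them all 51. DESeq2 gave 34 lower genes there, and the replicate block 19 higher ones. The causes of these changes were not tested. The tup1 libraries are not part of the WT contrast, but enter it through the shared spread, scaling and filter. Their replicate pairs scattered more (median chi-square per degree of freedom 10.23, against 2.093 in WT). The 51 calls are thus no measure of how far the WT strains differ. Pearson r across genes was 0.681 without the low-count filter and 0.798 with protein-coding genes only, against 0.773; the cause was not tested.

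Replicate numbers did not pair the libraries: residuals of the same number correlated at −0.292 to 0.121 over 18 pairs, and those of other numbers at −0.282 to 0.27 over 36. With the number as a block 2206 of 2342, 3482 of 3565, 1240 of 1349, 34 of 51 and 1863 of 1981 calls were shared, in the order above, and FLO11 was called in the interaction (−0.79, adjusted p = 0.00703).

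Leaving out each library in turn gave 617 to 1034 lower genes for tup1 in MATa, with 617 and 619 without WT MATa replicates 1 and 3, and 1243 to 1469 higher ones. In MATalpha there were 1671 to 1911 higher and 1519 to 1873 lower, and for the interaction 570 to 962 higher and 480 to 998 lower, the 998 without tup1 MATa replicate 1. For mating type in WT 11 to 179 were higher and 11 to 220 lower. Without tup1 MATa replicate 1 there were 179 and 220, among them all 51, and without tup1 MATa replicate 3 49 and 43. Without WT MATa replicates 1, 2 and 3 there were 13, 16 and 12 higher genes, and without WT MATalpha replicates 1, 2 and 3 there were 15, 16 and 11. Lower genes numbered 11 and 13 without WT MATa replicates 2 and 3 and 12, 13 and 13 without the WT MATalpha replicates. Genes lower in both mating types numbered 445 to 696, with 445 and 458 without WT MATa replicates 1 and 3. The cause of these shifts was not tested.

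Of 211 results for named genes, compared 4163 times in all, 4043 kept their direction and side of the threshold, 85 lost and 22 gained a call, and 13 turned direction, none of them called. With upper-quartile scaling TUP1 in MATalpha turned to −0.048, AFB1 to −0.09 and KSS1 to −0.106. Without single libraries the tup1 effect in MATalpha ranged from −0.175 to 0.04 for HO, −0.048 to 0.138 for AFB1 and −0.066 to 0.166 for KSS1, and the ANB1 interaction from −0.357 to 0.015. Mating type in WT ranged from −0.029 to 0.09 for CDC6 and −0.008 to 0.143 for RNR3, and in tup1 from −0.194 to 0.093 for STE2 and −0.116 to 0.027 for SUC2; the cause was not tested. Of 125 list results camera called 72, of which 18 kept their call with an estimated correlation and 54 lost it. With fry 63 of the 72 kept their call and 9 lost it, and 11 others gained one in the same direction. Fry asks whether the genes of a list change, and camera whether they change more than other genes. As many genes changed with tup1, a call by fry says little about a call by camera. G1/S genes with tup1 in MATa, for example, had adjusted p = 0.00672 with fry and 0.829 with camera. Phosphate genes with tup1 in MATa, not called by camera, turned from down to up with fry (adjusted p = 0.0374); the cause was not tested.

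Depth limited the genes near 0 counts: for those with 0 counts in a group only a lower bound of the fold can be given.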

Other observations

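The values in this part were chosen after the calls were seen, as were the core histone list and the test of iron genes.

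Of the 51 genes called between the WT strains, 39 with a position were not themselves a- or alpha-specific genes, and 6 of these (15.4%) lay within 2 kb of such a gene. Of genes not called, 0.557% did (odds ratio 32.5, two-sided Fisher's exact p = 1.51e-07). They were GYP8, 667 bp from STE2 (log2 fold change −0.89), SNR10, 832 bp from MF(ALPHA)2 (0.81), TOH1, next to ASG7 (−0.69), VID28, 1376 bp from BAR1 (−0.56), and YNL146C-A (−3.45) and YNL146W (1.57), 833 and 396 bp from MFA2. VID28 lost its call without WT MATa replicate 2 (adjusted p = 0.0717) or WT MATalpha replicate 3 (adjusted p = 0.0579).

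Core histone genes had a lower effect of tup1 in MATalpha than in MATa, with a median interaction of −0.54 and 7 of 8 genes called lower. In MATalpha 8 of 8 fell (median −0.82) and in MATa 4 of 8 (−0.20). The list was chosen after these calls were seen, so it is no test of a hold in G1.

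GRX3, a glutaredoxin that restrains the iron regulator Aft1, rose in tup1 MATalpha from 55.6 to 384 ± 87.6 CPM (SD, n = 3; log2 fold change 2.78, adjusted p = 1.73e-11) and did not pass in MATa (−0.28, adjusted p = 0.114). The effects differed (interaction 3.07, adjusted p = 1.59e-08). In MATa it was called lower with upper-quartile scaling (adjusted p = 0.0363), in a fit of the MATa libraries alone (adjusted p = 0.0148) and without tup1 MATalpha replicate 1 (adjusted p = 0.00329). If the rise of GRX3 were to lower the iron regulon, its genes might have a lower interaction than random lists. Their median interaction was −0.07, and 32.31% of random lists matched on expression lay as low, so this test did not set the list apart from chance. Iron genes lower in tup1 MATalpha than in tup1 MATa are the pattern that the hypothesis was made to explain. Their values are therefore no test of it. In WT the list was lower in MATalpha too, with 0 genes called (median −0.14, camera adjusted p = 0.0366, and adjusted p = 0.671 with an estimated correlation). In tup1, 6 iron genes were lower in MATalpha than in MATa and 1 higher (median −0.12, camera adjusted p = 0.0172, and adjusted p = 0.605 with an estimated correlation). Without tup1 MATalpha replicate 2, 15 were lower there, and 10 had a lower interaction with 1 higher, in place of 2 and 1. Between the tup1 strains 4 were lower and 1 higher without tup1 MATa replicate 1, and 8 and 1 without tup1 MATalpha replicate 1. The interaction was not of 1 direction: 3 were higher and 1 lower without tup1 MATa replicate 1, and 2 higher and 3 lower without tup1 MATalpha replicate 1. The list rose in both mating types, 15 of 25 genes in each, with medians of 0.43 in MATa and 0.41 in MATalpha. The hypothesis stays open.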
